A study of Mus musculus with 8 samples.

How the data were processed

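RNA was measured in iNKT cells from the skin (4 libraries) and the spleen (4 libraries) of mice with 1 EGFP allele at Ccr10. Per the labels' protocols, RNA was taken up with a micro-scale column kit, cDNA was made with a full-length ultra-low-input kit that does not mark the strand (SMART-Seq v4), and paired-end reads of 75 bp were made on a NextSeq 500. The deposited values are expected counts per gene, which RSEM estimates by sharing reads between the genes they match, per the submitters' processing notes; these also name FastQC, DESeq2 1.16.1 and the mouse build mm9, without their role or order. The aligner, the annotation release and any filter are not given in the sources used here. The values are not scaled for library size. Of all 22549 values in a library, zeros included, 12.3% to 19.4% were not whole. No coordinates are printed, because the reference at hand is of another build and was used for gene symbols only. Reads of paralogs, pseudogenes and overlapping or antisense genes cannot be told apart with certainty in such counts.

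Columns were assigned to libraries by the column names that the labels give as descriptions, and groups and replicate numbers come from the sample titles. The table holds 22549 genes, of which 11429 had a count above 0 in any library, and 0 columns of per-sample values were left unused. Expected counts were rounded to whole numbers. Library totals were 7221498, 9686050, 9791973 and 7371449 expected counts for skin replicates 1 to 4. They were 9361237, 8263897, 7461478 and 7191131 for spleen replicates 1 to 4. A floor of 3 counts corresponds to 0.292 to 0.454 CPM, and folds against a tissue with no count are lower bounds against this floor, taken per library and averaged over the tissue. Reads carry no molecular identifiers, so floors cover counting error only. They do not cover transcripts lost before sequencing, so these folds bound the counts and not the change in the cells.

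Genes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3: filterByExpr on the tissue groups left 6920 genes, library sizes were recomputed over them and scaled by TMM, and a robust quasi-likelihood fit (glmQLFit, glmQLFTest) with tissue as the only term was adjusted by Benjamini-Hochberg at 0.05. The common dispersion was 2.94, and the fit had 6 residual degrees of freedom. CPM use the TMM-scaled library sizes. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F, and is left out where a tissue has no count. Before the data were examined, 29 gene lists were fixed, 18 of biological programs and 11 of markers of other cell types, and 660 of their 667 symbols matched the table, some by an older symbol. Lists with at least 5 tested members were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01 and with an estimated correlation, adjusted over the 18 lists; the marker lists had fewer tested members with all 8 libraries and are given as summed CPM and counts. Some alternatives tested more lists, such as keratinocyte markers without a spleen library, and were adjusted over those too.

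The genes named were fixed by a rule set in advance: Ccr10, Zbtb16, Cd3e, Cd1d1 and Klrb1c whatever their values; the 12 genes higher and the 12 lower with the largest fitted log2 fold change among those called with at least 20 CPM in the higher tissue, no overlap between the tissues, no place on a marker list and a symbol that is not a predicted-gene, clone or small RNA name; up to 3 members higher and 3 lower of each list by adjusted p; the 5 genes with the smallest adjusted p in each direction under the same exclusions; and any list member given with its values beside its list. The other genes named, among them members of the GIMAP family and the genes that open the other observations, were chosen after their values were seen. Results for a few genes are not reported here.

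The same-numbered skin and spleen libraries were checked for pairing, and no 2 libraries agreed within sampling noise (the smallest chi-square per degree of freedom of a pair was 118). Library measures were compared by two-sided exact permutation tests. Alternatives fixed in advance were DESeq2's size factors (RLE) and upper-quartile scaling, no filter and a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, expected counts rounded down, the replicate number as a block, removal of marker genes of other cell types, removal of the 50 most abundant genes, each library left out, a TREAT test against 1.5-fold, and the estimated correlation. A fit of genes detected in at least 3 libraries of each tissue was added after seeing the data. All 35 splits of the 8 libraries into 4 and 4 were fitted.

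The fit was tested on simulated counts with 200 changed genes, 50 at each fold. With the spread of each gene as estimated here for skin against spleen (5931 genes tested), 0%, 2%, 6% and 14% of genes changed 2-, 4-, 8- and 16-fold were called, 1 gene was called in the wrong direction, and there were 0 false calls. With the spread of the 5% least variable genes (6912 genes tested), 4%, 72%, 100% and 100% were called, with 12 false calls. The list simulation used that same low spread for every gene and drew genes independently of each other. There, a list shifted 2-fold was called with the preset (camera adjusted p = 4.93e-12) and the estimated correlation (camera adjusted p = 0.00379). In the same simulation, 0 of 20 unchanged lists were called. It does not show how camera performs at the spread of these data or with correlated members, such as the immediate early list (estimated correlation 0.587).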

Results

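Transcripts of invariant natural killer T (iNKT) cells, T cells with a semi-invariant receptor that recognise lipids presented by CD1d, were measured by RNA sequencing in mice carrying 1 EGFP allele at the Ccr10 locus. There were 4 libraries of skin iNKT cells and 4 libraries of spleen iNKT cells. The design sets the transcriptome of skin iNKT cells against that of spleen iNKT cells. Total expected counts ranged from 7191131 to 9791973 per library. Their mean was 8517700 ± 1412200 in skin and 8069400 ± 974270 in spleen (SD, n = 4 each; two-sided exact permutation p = 0.6). The labels number the libraries 1 to 4 in each tissue and do not say that they came from separate animals. The p-values therefore measure the spread between these libraries, which may be technical. Gene levels are given in CPM (counts scaled to a common library total), as mean ± SD with n = 4 per tissue. Log2 fold changes are skin over spleen.

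Skin libraries held fewer genes. A count above 0 was found for 5304, 5302, 5954 and 6012 genes in skin replicates 1 to 4. It was found for 6415, 6897, 8690 and 10094 genes in spleen replicates 1 to 4. The means were 5643 ± 393 and 8024 ± 1692 (n = 4 each; two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give). The 50 most abundant genes took 20.4% ± 1.30 of the counts in skin and 15.2% ± 0.46 in spleen (two-sided exact permutation p = 0.0286, n = 4 each). Of the genes tested, 29.4% ± 3.63 stood at 0 in a skin library and 11.4% ± 10.2 in a spleen library. Spearman correlations across genes, which are not independent replicates, were 0.496 to 0.533 between skin libraries, 0.524 to 0.798 between spleen libraries and 0.321 to 0.479 between the tissues.

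**Figure D1:**
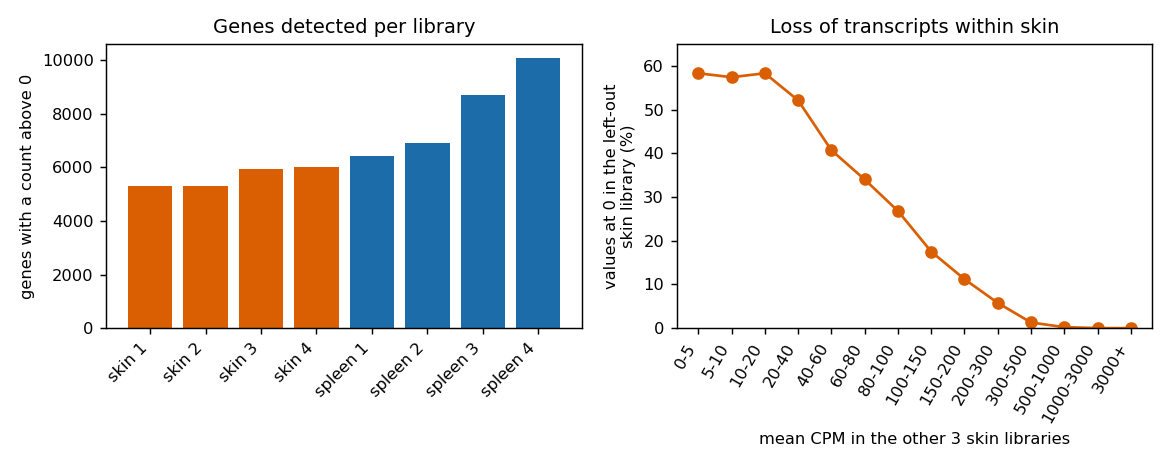
Left, number of genes with a count above 0 in each library, skin in orange and spleen in blue, with all 4 skin libraries below all 4 spleen libraries. Right, percentage of values at 0 in a left-out skin library against the mean CPM of the gene in the other 3 skin libraries, which is 58.3% at the lowest levels and 1.29% between 300 and 500 CPM.

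Skin iNKT cells carried more transcript of Rgs2, a regulator of G protein signalling, of the costimulatory receptor Icos, of the ferritin heavy chain Fth1 and of the store-operated calcium entry regulator Tmem66. They carried less of the immune-associated GTPase Gimap4, the GTPase Rac2, the adhesion receptor Cd97 and Limd2. Rgs2 stood at 5597 ± 226 CPM in skin and 120 ± 82.3 CPM in spleen, a log2 fold change of 5.55 ± 0.48 (SE; edgeR adjusted p = 0.00128). Tmem66 was 9.40-fold higher (2943 ± 540 against 313 ± 21.6 CPM; edgeR adjusted p = 9.20e-05). Fth1 was 4.72-fold higher (8492 ± 744 against 1798 ± 366 CPM; edgeR adjusted p = 0.000361). The translation initiation factor Eif1 was 2.88-fold higher, at 2980 ± 136 against 1034 ± 96.7 CPM. Gimap4 had no count in any skin library and 3165 ± 336 CPM in spleen. It was at least 8176-fold lower in skin against a floor of 3 counts per library (edgeR adjusted p = 1.63e-05). Here and below, such bounds cover counting error only, not transcripts lost before sequencing. Rac2 fell from 4872 ± 328 CPM in spleen to 1159 ± 208 CPM in skin. Cd97 fell from 1342 ± 76.2 to 373 ± 54.8 CPM and Limd2 from 898 ± 83.3 to 159 ± 29.7 CPM. Tmsb4x, which encodes the actin-binding peptide thymosin beta 4, fell by 0.94 on the log2 scale (SE 0.092).

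Of 6920 genes tested with edgeR's quasi-likelihood test, 128 were higher and 248 lower in skin at a Benjamini-Hochberg adjusted p under 0.05. Of these, 122 and 244 differed at least 2-fold. All 4 skin libraries stood at 0 for 182 of the 248 lower genes, while 66 had a count in skin. In spleen, 13 of the 128 higher genes stood at 0 in all 4 libraries. Among the 2237 tested genes detected in all 8 libraries, 110 were higher and 47 lower. The skin and spleen values did not overlap for 375 of the 376 called genes and for 1349 of the genes tested (19.5%, where chance gives 2.86%). The counts rest on values close to the threshold: 253 of the 376 genes had an adjusted p from 0.04 to 0.05, 162 of them at 0 in every skin library. Leaving out 1 library left 47 to 102 higher and 17 to 111 lower genes. Among genes detected in at least 3 libraries of each tissue, a restriction chosen after seeing the data, 102 were higher and 46 lower. In all 8 fits that left out 1 library, 35 of the higher and 15 of the lower genes were called again. The higher ones included Rgs2, Icos, Tmem66, Fth1, Eif1, Nr4a2, Tubb2a, Cd44, Rora, Dnaja1, Hspa8 and Gapdh, and the lower ones Gimap4, Gimap7, Rac2, Limd2, Cd97, Tmsb4x, Ly6c2, Dtx1, Asb2 and Folr4. Each other called gene that the rule set in advance names lost its call in at least 1 of them. Counts of called list members above 0 are followed below by their range over these 8 fits where it varied.

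The largest changes among genes at 0 in 1 tissue included the orphan nuclear receptor Nr4a2, at 580 ± 482 CPM in skin and 0 in all 4 spleen libraries (at least 1539-fold higher; edgeR adjusted p = 0.00512). The beta-tubulin Tubb2a stood at 307 ± 181 CPM in skin and 0 in spleen (at least 814-fold higher). Calca, which encodes calcitonin and calcitonin gene-related peptide, stood at 173 ± 198 CPM in skin and the protease Ctsl at 172 ± 62.3 CPM. The urokinase receptor Plaur stood at 130 ± 77.2 CPM, Spsb1 at 139 ± 109 CPM and the autophagy protein Gabarapl1 at 109 ± 46.97 CPM. None of these 5 had a count in spleen. Sdc4, Rgmb, Ndrg1, Itga1 and Fam132a followed, at 99.8 ± 26.5, 88.8 ± 45.6, 83.0 ± 39.2, 77.9 ± 49.7 and 61.5 ± 17.6 CPM. Calca, Spsb1, Plaur, Gabarapl1, Sdc4, Rgmb, Ndrg1, Itga1 and Fam132a lost their calls in each of the 8 fits without 1 library, while Nr4a2 and Tubb2a kept theirs. Ctsl, Spsb1, Plaur, Gabarapl1, Sdc4, Rgmb, Ndrg1, Itga1 and Fam132a stayed below the summed keratinocyte markers in every skin library. With no count in skin, Dtx1, a Notch pathway ubiquitin ligase, stood at 482 ± 207 CPM in spleen (at least 1245-fold lower). Asb2 stood at 349 ± 101 CPM and Gimap7 at 317 ± 46.5 CPM. Rgs3 stood at 271 ± 113 CPM, Ganab at 222 ± 62.5 CPM and the ATP-gated channel P2rx7 at 198 ± 99.0 CPM. Dtx1, Asb2 and Gimap7 were called in each fit without 1 library. Rgs3 was lost without spleen replicate 3, Ganab without spleen replicates 2 or 3, and P2rx7 without any 1 of the spleen libraries.

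Of 22 measured members of the tissue residency list, which marks lymphocytes that stay in tissues, 4 were higher in skin (3 to 4), 0 lower and 18 did not pass. Residency genes numbered 7 higher and 0 lower adjusted over the list alone. The list stood above the other genes in camera with the preset correlation (adjusted p = 2.57e-09) and did not pass with an estimated one (adjusted p = 0.0748). The 4 were Icos (3303 ± 486 against 621 ± 81.8 CPM), Rgs2, Nr4a2 and the alpha 1 integrin Itga1. Nr4a1, Nr4a2 and Nr4a3 are on the immediate early list too, and tissue and handling go together for both lists. The alpha E integrin Itgae stood at 631 ± 388 CPM in skin and 3.79 ± 7.58 CPM in spleen, with its 1 spleen value above 0 in replicate 4 (edgeR adjusted p = 0.12, not called). Without spleen replicate 4 it was called (edgeR adjusted p = 0.00387). Rgs1 (3325 ± 794 against 98.7 ± 116 CPM) and Litaf (2784 ± 768 against 60.1 ± 99.1 CPM) did not overlap between the tissues and did not pass the test. The same held for Nr4a1 (1299 ± 661 against 43.7 ± 63.1 CPM) and the early activation antigen Cd69 (572 ± 133 against 74.4 ± 64.5 CPM). On the log2 scale 18 of the 22 members were above 0 and 4 below. Among the latter, Isg20 did not overlap between the tissues (20.3 ± 26.0 against 103 ± 26.6 CPM, not called). In the circulation list, which holds genes of recirculating lymphocytes, 3 of 20 members were lower (1 to 3) and 0 higher. Circulation genes numbered 6 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.000122; adjusted p = 0.0784 with an estimated correlation). Ly6c2 fell from 1363 ± 91.9 to 347 ± 82.6 CPM (edgeR adjusted p = 0.00341). The transcription factor Klf3 fell from 180 ± 63.2 CPM to no count, and the alpha 4 integrin Itga4 from 49.3 ± 33.2 to 0.0654 ± 0.0773 CPM. The call of Klf3 was lost without any 1 of the spleen libraries, and that of Itga4 in each fit without 1 library. Genes at 40 to 60 CPM in the other skin libraries stood at 0 in 40.7% of skin values. Tcf7 stood at 184 ± 58.5 CPM in skin and 389 ± 95.3 CPM in spleen. The interleukin 7 receptor gene Il7r stood at 262 ± 267 and 629 ± 131 CPM. Neither passed the test.

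**Figure D2:**
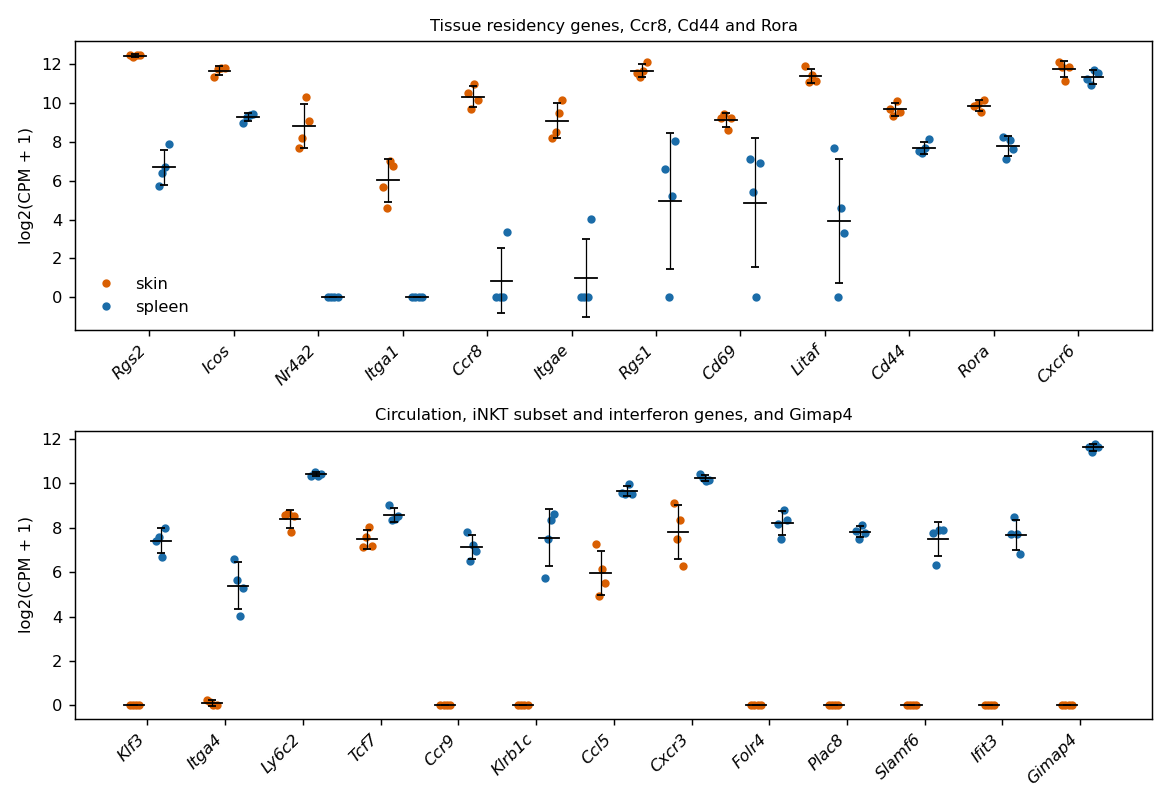
Level of each gene, as log2(CPM + 1), in the 4 skin (orange) and 4 spleen (blue) libraries, with the mean as a bar and the SD as whiskers. Rgs2, Icos, Cd44 and Rora are higher in every skin library than in any spleen library, and Klf3, Ccr9, Klrb1c, Folr4, Plac8, Slamf6, Ifit3 and Gimap4 have no count in skin.

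The list of skin homing and chemoattractant receptors did not pass as a group, with 1 higher (0 to 1), 2 lower (0 to 2, and 0 without any 1 of the spleen libraries) and 10 not passing of 13. Receptor genes numbered 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.533; adjusted p = 0.543 with an estimated correlation). Ccr8, a chemokine receptor of skin T cells, rose from 2.30 ± 4.61 CPM in spleen to 1361 ± 503 CPM in skin (log2 fold change 9.22 ± 2.10, SE; edgeR adjusted p = 0.0473). Its 1 spleen value above 0 was in replicate 4. The call held in 1 of the 8 fits without a library, that without spleen replicate 4. The gut homing receptor Ccr9 fell from 147 ± 57.8 CPM to no count in skin, and its call was lost without any 1 of the spleen libraries. In counts it was at least 381-fold lower. Genes at 100 to 150 CPM in the other skin libraries stood at 0 in 17.5% of skin values, so the fold in the cells may be smaller. Itga4 was the other lower member. On the log2 scale 7 of the 13 members were above 0 and 6 below, and the camera direction was higher in skin. Ccr10, the receptor whose locus carries EGFP, stood at 20.5 ± 23.7 CPM in skin and 19.6 ± 17.3 CPM in spleen. Its log2 fold change was 0.06 ± 2.55 (SE; edgeR adjusted p = 0.999), and the values did not show whether it differed. Cxcr3 stood at 283 ± 207 CPM in skin and 1205 ± 116 CPM in spleen (edgeR adjusted p = 0.0542). Ccr2 stood at 301 ± 184 and 632 ± 191 CPM, and Cxcr6 at 3518 ± 901 and 2660 ± 622 CPM. None of these 3 was called.

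The iNKT identity and T cell receptor list held 1 higher and 3 lower members of 22 (1 higher and 0 to 5 lower, 0 without spleen replicates 3 or 4). Identity genes numbered 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.533; adjusted p = 0.742 with an estimated correlation). Cd44, the hyaluronan receptor of antigen-experienced T cells, rose from 211 ± 50.7 to 837 ± 204 CPM (log2 fold change 1.98 ± 0.27, SE; edgeR adjusted p = 0.00808). Klrb1c, which encodes NK1.1, fell from 237 ± 152 CPM to no count (at least 613-fold lower; edgeR adjusted p = 0.0187; lost without spleen replicates 2, 3 or 4). The SLAM family receptor Slamf6 fell from 194 ± 76.8 CPM to no count (lost without spleen replicates 1, 3 or 4). Cd3d fell from 1112 ± 226 to 470 ± 83.9 CPM. Cd3e stood at 589 ± 252 and 528 ± 43.3 CPM in skin and spleen (log2 fold change 0.16 ± 0.30, SE). Zbtb16, the transcription factor of the iNKT lineage, stood at 44.5 ± 25.7 and 66.6 ± 63.0 CPM, and Cd1d1 at 46.4 ± 54.7 and 58.0 ± 13.1 CPM. None of these 3 was called. Of 27 members of the iNKT1 list 0 were higher and 3 lower (1 to 4). On the log2 scale 17 of the 27 were above 0 and 10 below, and the camera direction was higher in skin. The iNKT1 genes numbered 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.142; adjusted p = 0.456 with an estimated correlation). The lower members were Ly6c2, Klrb1c and the chemokine Ccl5, which fell from 808 ± 140 to 74.4 ± 55.2 CPM (edgeR adjusted p = 0.0135; lost without spleen replicate 3). Gzmb stood at 230 ± 151 CPM in skin and 35.7 ± 10.6 CPM in spleen and was not called. Tbx21 stood at 350 ± 237 and 247 ± 171 CPM and was not called. In the iNKT2 list 1 of 12 members was higher, Icos, and 3 were lower (1 to 4). The iNKT2 genes numbered 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00811; adjusted p = 0.292 with an estimated correlation). The lower members were Folr4, at 311 ± 109 CPM in spleen, Plac8, at 227 ± 39.6 CPM, and Slamf6, all with no count in skin. Gata3 stood at 122 ± 81.7 CPM in skin and 171 ± 75.9 CPM in spleen. In the iNKT17 list 1 of 12 was higher, the orphan nuclear receptor Rora (949 ± 172 against 230 ± 72.8 CPM; edgeR adjusted p = 0.0099). None was lower, and the list numbered 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.313; adjusted p = 0.39 with an estimated correlation). On the log2 scale 6 of the 12 were above 0 and 6 below. Ramp1 stood at 45.4 ± 33.6 CPM in skin and 415 ± 85.0 CPM in spleen and was not called. In the other direction 5830411N06Rik stood at 621 ± 448 CPM in skin and 57.0 ± 44.55 CPM in spleen, and was not called either.

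Immediate early genes, which are transcribed within minutes of a stimulus, stood above the other genes in skin as a list (camera adjusted p = 3.58e-11; adjusted p = 0.13 with an estimated correlation). Of its 20 members 1 passed on its own (1 to 8), Nr4a2 (1 higher and 0 lower adjusted over the list alone). Spleen replicate 4 stood apart in this list. Fos, a subunit of the AP-1 transcription factor, stood at 950 CPM there and at no more than 0.1 CPM in the other spleen libraries, against 1377 ± 530 CPM in skin. Junb stood at 3048 CPM there and at 157 to 236 CPM in the others, against 5884 ± 1635 CPM in skin. Without spleen replicate 4, 8 members were higher and 0 lower (camera adjusted p = 1.55e-15; adjusted p = 0.0937 with an estimated correlation). They were Fos (edgeR adjusted p = 0.000398), Junb (0.000308), Atf3 (0.00226), Ppp1r15a (0.0034), Zfp36 (0.00476), Fosl2 (0.0109), Ier2 (0.025) and Nr4a2 (0.00997). With all 8 libraries Ppp1r15a stood at 1447 ± 427 against 315 ± 544 CPM. Levels were 254 ± 113 against 1.49 ± 2.97 CPM for Fosl2 and 530 ± 195 against 4.98 ± 9.96 CPM for Atf3. Dusp1, a phosphatase of MAP kinases, stood at 2129 ± 1500 and 595 ± 963 CPM and was called in neither fit.

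**Figure D3:**
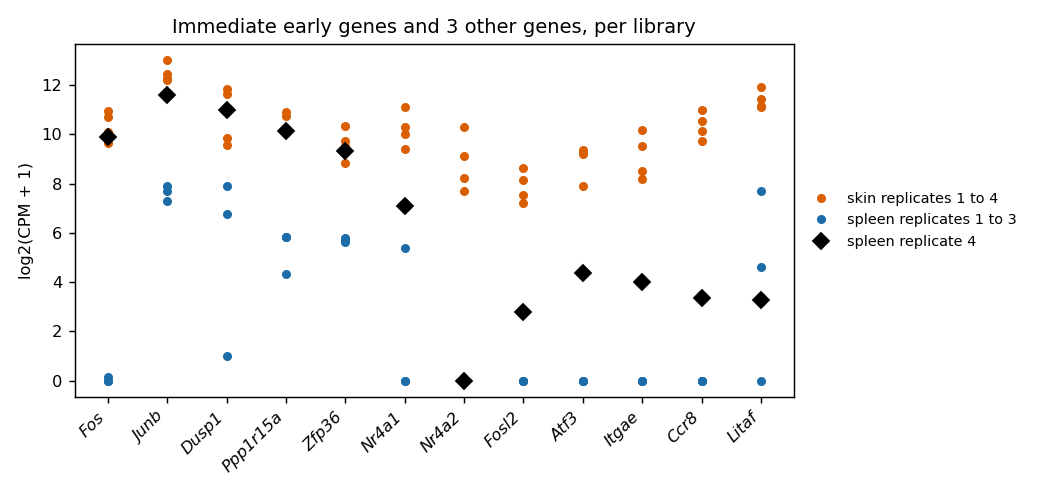
Level per library, as log2(CPM + 1), of 9 immediate early genes and of Itgae, Ccr8 and Litaf, with skin in orange, spleen replicates 1 to 3 in blue and spleen replicate 4 as black diamonds. Fos stands at 950 CPM in spleen replicate 4, inside the range of the skin values, while the other spleen values are at most 0.1 CPM.

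Of 13 heat shock genes 5 were higher in skin (2 to 4, and 2 without spleen replicate 4) and 0 lower. Heat shock genes numbered 6 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000341; adjusted p = 0.13 with an estimated correlation). The co-chaperone Dnaja1 rose from 322 ± 80.5 to 1979 ± 335 CPM (log2 fold change 2.62 ± 0.23, SE; edgeR adjusted p = 0.00128), and the chaperone Hspa8 from 1634 ± 268 to 4211 ± 684 CPM. Hsp90ab1 rose from 1140 ± 150 to 3369 ± 1263 CPM and Hsp90aa1 from 326 ± 127 to 1186 ± 382 CPM. Hspa5, the chaperone of the endoplasmic reticulum, rose from 1175 ± 345 to 2398 ± 563 CPM and was called in none of the fits without 1 library. Of 23 targets of NF-kappaB 4 were higher (1 to 3) and 0 lower. NF-kappaB targets numbered 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000978; adjusted p = 0.106 with an estimated correlation). The higher genes included the autophagy receptor Sqstm1 (2196 ± 567 against 704 ± 161 CPM) and the adhesion molecule Icam1 (1086 ± 329 against 375 ± 74.7 CPM). The others were Tnfaip8 (880 ± 101 against 178 ± 100 CPM) and Bcl2a1b (766 ± 208 against 280 ± 63.0 CPM), which has near-identical paralogs that may share its reads. Interferon-stimulated genes were lower in 3 of 19 members (0 to 4) and higher in 0. Interferon genes numbered 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 9.39e-05; adjusted p = 0.0648 with an estimated correlation). Ifit3 fell from 221 ± 99.3 CPM to no count (edgeR adjusted p = 0.0127). The RNA sensor Dhx58 fell from 88.7 ± 60.4 CPM to no count and Xaf1 from 113 ± 36.6 to 0.637 ± 0.803 CPM. The call of Ifit3 was lost without spleen replicates 1, 2 or 3, and 0 members were called lower in those fits. The call of Dhx58 was lost in each fit without 1 library, and that of Xaf1 in each except the fit without skin replicate 4. On the log2 scale 17 of the 19 members were below 0 and 2 above. Isg15, 1 of the latter, stood at 85.6 ± 43.9 CPM in skin and 25.6 ± 5.42 CPM in spleen and was not called. Irf9 stood at 16.1 ± 32.2 CPM in skin and 354 ± 68.1 CPM in spleen without passing the test.

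Genes of glycolysis and hypoxia were higher in 4 of 22 members (1 to 4) and lower in 0. Glycolysis genes numbered 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.63e-05; adjusted p = 0.0784 with an estimated correlation). Gapdh rose from 2152 ± 260 to 6347 ± 1790 CPM and the aldolase gene Aldoa from 863 ± 89.7 to 1780 ± 254 CPM. The lactate dehydrogenase gene Ldha rose from 2094 ± 388 to 4188 ± 1050 CPM. Ndrg1 was the other member called. Without spleen replicate 4, 1 member was called, Gapdh. Of 42 nuclear-encoded respiratory chain genes 3 were lower (0 to 3, and 0 without any 1 of the spleen libraries) and 0 higher. Respiratory chain genes numbered 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0178; adjusted p = 0.084 with an estimated correlation). The 3 were Atp5j (131 ± 43.8 against 440 ± 59.8 CPM), Sdhb (127 ± 31.3 against 364 ± 42.3 CPM) and Sdha (146 ± 64.6 against 445 ± 54.8 CPM). Sdhb was called in 0 and Sdha in 1 of the 8 fits without a library. Of 50 cytoplasmic ribosomal protein genes 6 were lower (0 to 3, and 0 without any 1 of the spleen libraries) and 0 higher. Ribosomal genes numbered 16 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.0226; adjusted p = 0.39 with an estimated correlation). Rps27a fell from 464 ± 129 to 148 ± 26.3 CPM, Rps18 from 861 ± 179 to 356 ± 83.1 CPM and Rps19 from 912 ± 82.1 to 496 ± 52.4 CPM. Rps18 was called in none of the fits without 1 library. Many ribosomal protein genes have processed pseudogenes that may share their reads.

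**Figure D4:**
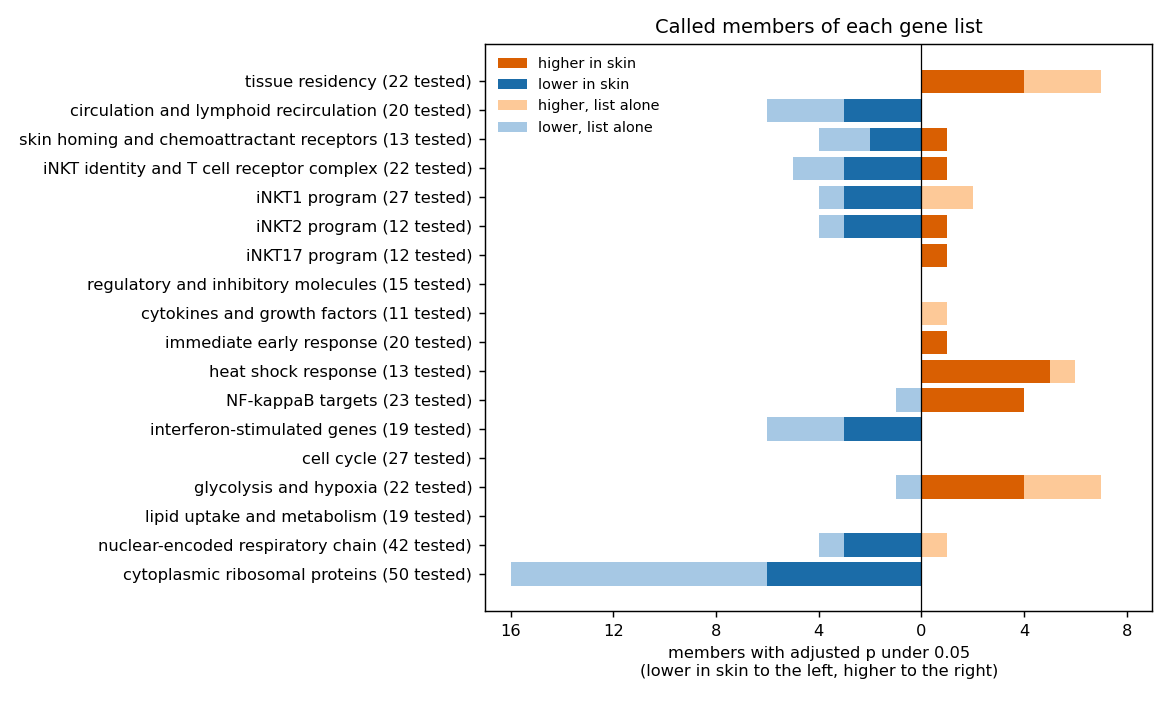
Number of members of each of the 18 tested gene lists that were higher (right) or lower (left) in skin at an adjusted p under 0.05, over all genes tested (dark) and adjusted over the list alone (light extension). Tissue residency and glycolysis reach 7 higher members, and cytoplasmic ribosomal proteins reach 16 lower members, adjusted over the list alone.

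In 4 lists 0 members passed over all genes with all 8 libraries. Regulatory and inhibitory molecules (15 tested) stood above the other genes in skin (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0113; adjusted p = 0.13 with an estimated correlation). In skin and spleen Tgfb1 stood at 244 ± 104 and 37.5 ± 13.5 CPM (edgeR adjusted p = 0.0551) and the inhibitory receptor Cd160 at 55.9 ± 54.6 and 572 ± 208 CPM. In the fits without 1 library 0 to 1 of the regulatory genes were higher and 0 to 1 lower, and Nfil3 was the higher one without spleen replicate 4 (edgeR adjusted p = 0.0168). Counts of 0 also rose to 1 in some of these fits for lower iNKT17, NF-kappaB and glycolysis genes and for higher respiratory chain genes. Cytokines and growth factors (11 tested; 1 higher and 0 lower adjusted over the list alone) stood higher in skin (camera adjusted p = 0.0226; adjusted p = 0.13 with an estimated correlation). Genes of lipid uptake and metabolism (19 tested; 0 higher and 0 lower adjusted over the list alone) stood higher too (camera adjusted p = 0.00173; adjusted p = 0.151 with an estimated correlation). Cell cycle genes (27 tested; 0 higher and 0 lower adjusted over the list alone) did not pass as a list (camera adjusted p = 0.248; adjusted p = 0.424 with an estimated correlation). In all, 13 of the 18 lists passed with the preset correlation, 8 higher and 5 lower in skin, and 0 passed with an estimated correlation.

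Markers of other cell types were summed per library, and 3 single markers were called. The 18 keratinocyte markers summed to 721 ± 485 CPM in skin and 11.4 ± 12.8 CPM in spleen. Perp, a desmosome gene, was the 1 called member of 3 tested (153 ± 55.5 CPM against no count; edgeR adjusted p = 0.0328). Erythroid and platelet markers summed to 0.53 ± 1.06 CPM in skin and 226 ± 80.3 CPM in spleen. The globin genes Hba-a1 (0.106 ± 0.212 against 119 ± 20.8 CPM) and Beta-s (no count against 40.8 ± 11.4 CPM) were both lower. Globin genes have near-identical copies. B cell and plasma cell markers summed to 0 in skin and 98.9 ± 55.1 CPM in spleen. Markers of gamma-delta and CD8 T cells summed to 195 ± 161 and 44.2 ± 26.9 CPM. Sums in skin and spleen were 242 ± 138 and 188 ± 164 CPM for myeloid and antigen-presenting cells and 23.5 ± 40.5 and 86.0 ± 44.7 CPM for neutrophils. They were 66.2 ± 75.6 and 44.8 ± 72.5 CPM for fibroblasts and 30.8 ± 8.59 and 48.8 ± 31.3 CPM for melanocytes and Schwann cells. They were 95.8 ± 71.7 and 81.4 ± 62.9 CPM for NK and innate lymphoid cells, 0 and 3.28 ± 6.56 CPM for endothelium and 0.0284 ± 0.0568 and 0.223 ± 0.446 CPM for mast cells and basophils. In these lists, 0 to 3 members of each were tested and 0 were called.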

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

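Chosen only after the results were seen were the tests of sequencing depth, of skin RNA in spleen replicate 4, of keratinocyte RNA, and the 2 tests that divide the genes at 0 in skin by abundance; the tests of transcript loss over all such genes, of handling before lysis and of other splits were set before.

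For a library far from the rest, 215 groups of 4 values were tested on the log2(CPM + 1) scale. In 26 of them the gap, as a share of the group's range, was over Dixon's 95% critical value. The chance rate of about 1 in 20 holds for normal values and not for these groups. Where 1 library alone is above 0, the share is 1 at any level. Spleen replicate 4, the library with most genes detected (10094), was the library apart in 11 of the 26. It was the highest spleen library for Fos (0.992 of the range, 950 CPM), Junb (0.863, 3050 CPM), Zfp36 (0.95, 638 CPM) and, at low levels with no count in the other spleen libraries, for Atf3 (1, 19.9 CPM), Fosl2 (1, 5.95 CPM), Ccr8 (1, 9.22 CPM), Itgae (1, 15.2 CPM), Nfil3 (1, 22.6 CPM) and Cdkn1a (1, 2.53 CPM), and the lowest for Rac2 (0.901, 4380 CPM) and Limd2 (0.864, 774 CPM). Spleen replicate 1 was lowest for Gimap7 (0.867, 248 CPM), Gimap3 (0.885, 1630 CPM) and Map1lc3b (0.865, 291 CPM), spleen replicate 2 for Slamf6 (0.902, 79.4 CPM) and Tbx21 (0.936, no count), and spleen replicate 3 was highest for Ccl5 (0.919, 1020 CPM). Skin replicate 1 was lowest for Icos (0.918, 2580 CPM), Atf3 (0.904, 240 CPM) and Gimap6 (0.964, no count), and skin replicate 3 for Ly6c2 (0.832, 225 CPM). Skin replicate 4 was lowest for Ramp1 (0.852, no count) and highest for Irf9 (1, 64.4 CPM), Xaf1 (0.854, 1.84 CPM), Gimap5 (0.848, 0.847 CPM) and Hba-a1 (1, 0.424 CPM).

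In the immediate early list, 18 tested genes with at least 20 CPM in skin stood at least 2-fold above spleen replicates 1 to 3, and some of them, Fos and Junb included, were high in spleen replicate 4 too, while Nr4a2 had no count there. Skin RNA mixed into that library is argued against: 53 genes outside the immediate early and heat shock lists that were called at least 2-fold higher in skin without that library reached a median of 3.1% of their skin excess there (quartiles 0 and 12.1%), against 51.4% for immediate early genes (15.5% and 76.9%). Handling of the tissue before lysis, which can induce these genes, cannot be told apart from the tissue, because all skin cells came from skin and the labels give no handling times. The bound set beforehand against handling, an adjusted p of 0.05 or more for the list with an estimated correlation and without spleen replicate 4, was met at 0.0937, and the verdict was changed to open afterwards: a p over the threshold does not show that the list did not differ, and 8 members, Fos and Junb among them, were called higher in that fit. The residency (adjusted p = 0.0302) and interferon lists (adjusted p = 0.0484) did pass with an estimated correlation in the same fit, so the test could be passed there, and the verdict rests on the design, in which tissue and handling go together. A difference between the tissues in the cells' own activation stays open and untested.

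Of genes detected in all 4 spleen libraries, 281 had no count in any skin library. The loss of genes of the same abundance from one skin library to the others gives 115 ± 10.3 (SD). Loss in skin libraries of low complexity, at 1 rate for genes of the same abundance, does not account for all of them. The parts differ: with a spleen mean of at least 20 CPM, 240 genes stood at 0 where 61.3 ± 7.62 were expected, 167 of them called, and under 20 CPM 41 stood at 0 where 53.6 ± 6.89 were expected, 15 of them called, so loss may account for the second part. At 200 CPM or more, 10 genes stood at 0 where 0.00494 were expected, Gimap4, Dtx1, Asb2, Gimap7, Folr4, Rgs3, Klrb1c, Plac8, Ganab and Ifit3. Lower depth is argued against, since the mean total of the skin libraries was 1.06 times that of the spleen libraries. The expectation assumes that genes of the same abundance share 1 loss rate and that a gene is lost independently in each skin library. The rates were taken at the level in the other skin libraries, where a consistently lost gene stands low. A gene lost more readily than others of its abundance would add to the excess. Loss is therefore not excluded, and a biological difference between the tissues stays open.

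Keratinocyte markers summed to 273 to 1194 CPM in the skin libraries. As a list they stood higher in skin without spleen replicate 4, where 5 or more of them could be tested (camera adjusted p = 8.53e-05; adjusted p = 0.106 with an estimated correlation). Keratinocyte RNA was weighed as a source of the 127 other genes called higher, and the values do not exclude it. The summed markers were 3.75 times as high in skin replicates 1 and 3 as in replicates 2 and 4. Single markers had a lower quartile of 2.31. The excess of the called genes over spleen had a median ratio of 1.12 (quartiles 0.875 and 1.35, range 0.119 to 2.91). The markers Krt17 (0.858), Sfn (2.52) and Perp (1.71), which was the 1 called marker, lay within that range. A gene that varies between skin libraries as the summed markers do is less likely to be called. Low ratios among called genes were thus favoured in advance. This test replaced a bound on abundance, which assumed a keratinocyte profile, and rests on 4 libraries and on the markers following the keratinocyte share. Keratinocyte RNA stays open as a source, also for single genes such as Perp, itself a marker. The same holds for Ctsl, Spsb1, Plaur, Gabarapl1, Sdc4, Rgmb, Ndrg1, Itga1, Fam132a and Nfe2l2, which stayed below the summed markers in every skin library.

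In other splits of the 8 libraries, 1 of 35 splits, the real one, gave as many called genes (376, highest other 0). The real split also gave the most genes at least 2-fold apart (366, highest other 0) and the most called lists with the preset correlation (13, highest other 11). That is the smallest share that 35 splits can give. Every other split puts both tissues on each side, which adds the tissue difference to the spread within groups and can lower the counts. Chance is not excluded, since the labels do not say that the libraries came from separate animals. With an estimated correlation 0 lists were called in the real split. The 11 lists came from the split that sets skin replicates 1, 3 and 4 and spleen replicate 4 against the rest, which keeps 3 libraries of a tissue on each side.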

How the results depend on the processing

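The fit restricted to genes detected in at least 3 libraries of each tissue was chosen only after the data were seen. RLE and upper-quartile scaling, the stricter filter, rounding down and removal of marker genes kept the counts of 128 higher and 248 lower genes within 1.5 times, and the scalings moved the median log2 fold change of tested genes from -0.29 to -0.23 and -0.24. DESeq2 called 295 higher and 447 lower (278 and 434 at least 2-fold) and left 186 adjusted p as NA, and limma-voom called 207 and 500 (188 and 495), moved the median to -2.06 and lost the calls of Gimap4, Fth1, Ftl1, Tmsb4x, Gapdh, Vps37b, Crem, Sdhb, Coro1a and Ptpn6; the cause was not tested. With no filter, a fit of 11429 genes, 97 were higher and 48 lower (46 lower at least 2-fold). Without the 50 most abundant genes 56 were higher and 48 lower (53 and 47 at least 2-fold); the cause was not tested. Among genes detected in at least 3 libraries of each tissue 102 were higher and 46 lower (43 lower at least 2-fold), of which 102 and 42 were called in the full comparison, since genes at 0 in skin are left out. TREAT against 1.5-fold left 51 higher and 35 lower. Leaving out each library in turn, which leaves fewer samples, gave 47 to 102 higher and 17 to 111 lower genes, 45 to 97 and 15 to 106 at least 2-fold; the fewest lower genes, 17, 20, 22 and 25, came without spleen replicates 3, 4, 2 and 1, and the most without skin replicate 4.

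Of the 18 lists 13 were called, 11 to 13 without 1 library, 8 among genes detected in at least 3 libraries of each tissue and 0 with an estimated correlation. The iNKT2 list changed direction in that restricted fit, without passing (adjusted p = 0.25); without spleen replicate 4 the residency (adjusted p = 0.0302) and interferon lists (adjusted p = 0.0484) passed with an estimated correlation. Without any 1 of the spleen libraries a list of keratinocyte markers was tested as a 19th and called higher in skin (camera adjusted p from 9.69e-06 to 8.53e-05). These p are with the preset correlation, and p in those fits are adjusted over 19 lists. Without spleen replicate 4 and with an estimated correlation the keratinocyte list did not pass (camera adjusted p = 0.106). With no filter 25 lists were tested with the preset correlation. Keratinocyte (camera adjusted p = 7e-08) and fibroblast markers (0.0481) were called higher and erythroid and platelet markers (0.00221) lower.

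Same-numbered skin and spleen libraries did not visibly deviate together (correlations of 0.0017 to 0.011 over 4 pairs). Differently numbered pairs gave -0.027 to 0.043. Libraries of a tissue differed widely (common dispersion 2.94), so a shared animal might not show. Whether same-numbered libraries share an animal is not given in the labels and stays open. With the replicate number as a block, 36 genes were higher and 14 lower (36 and 13 at least 2-fold) and 12 lists were called.

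The spread between libraries limits what can be called: with the spread as estimated, simulated 16-fold changes were called for 14% of genes, against 100% with that of the least variable genes, so a gene that did not pass was not shown to be unchanged.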

Other observations

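The genes in the next paragraph and the test of the GIMAP family were chosen after their values were seen.

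Ftl1, the ferritin light chain, stood at 5590 ± 1145 CPM in skin and 1987 ± 248 CPM in spleen (edgeR adjusted p = 0.00387), the polyubiquitin gene Ubb at 12730 ± 2662 and 5537 ± 1146 CPM, and Map1lc3b at 1640 ± 559 and 468 ± 120 CPM; ferritin and ubiquitin genes have pseudogenes that may share their reads. The glucocorticoid receptor gene Nr3c1 stood at 807 ± 242 against 133 ± 47.2 CPM (edgeR adjusted p = 0.00901), the cAMP-responsive modulator Crem at 4410 ± 671 against 10.5 ± 12.1 CPM (0.0463), Vps37b at 7125 ± 1250 against 130 ± 93.0 CPM (0.00231), Cytip at 2172 ± 786 against 197 ± 107 CPM (0.00834), the galectin Lgals1 at 1511 ± 399 against 412 ± 34.3 CPM (0.00373), the cell cycle inhibitor Cdkn1a at 652 ± 257 against 0.632 ± 1.26 CPM (0.0343), Cebpb at 422 ± 169 against 91.5 ± 49.4 CPM (0.0473) and Nfe2l2 at 458 ± 136 against 126 ± 54.4 CPM (0.0473). Lower in skin were the proteasome activator genes Psme1 (243 ± 92.2 against 739 ± 149 CPM; edgeR adjusted p = 0.0411) and Psme2 (304 ± 88.8 against 897 ± 121 CPM; 0.0243), the actin regulator Coro1a (1898 ± 527 against 4202 ± 474 CPM; 0.025), the beta 2 integrin Itgb2 (520 ± 186 against 1514 ± 278 CPM; 0.0308), the phosphatase Ptpn6 (174 ± 32.7 against 630 ± 211 CPM; 0.0247), Cd52 (1154 ± 192 against 3218 ± 298 CPM; 0.00256) and Ms4a4b (622 ± 307 against 2187 ± 114 CPM; 0.037). Of these, Ftl1, Nr3c1, Vps37b, Cytip, Lgals1 and Cd52 were called in all 8 fits without 1 library. Crem, Cebpb and Nfe2l2 were called in at most 1 of them, and the rest of these genes in 2 to 5.

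The GIMAP family, GTPases of lymphocyte survival, had 8 members in the table, with a summed level of 298 ± 49.2 CPM in skin and 8590 ± 801 CPM in spleen (n = 4 each). Gimap4, Gimap7 and Gimap5 were called; Gimap3 (33.5 ± 59.5 against 1913 ± 190 CPM), Gimap6 (119 ± 80.01 against 1959 ± 409 CPM) and Gimap1 (33.9 ± 40.8 against 700 ± 86.1 CPM) were not, nor were Gimap9 (91.1 ± 63.8 against 236 ± 41.3 CPM; edgeR adjusted p = 0.455) and Gimap8 (20.7 ± 41.0 against 92.1 ± 27.6 CPM; 0.998). Gimap5 kept its call in 1 of the 8 fits without 1 library. A hypothesis is that the family may be lowered as a group. Gimap4 and Gimap7 drew attention to it, so the test was made on the other 6 members, all below 0 on the log2 scale: their camera p with an estimated correlation was 0.0142 (not adjusted), and it was 0.00205 over all 8. Members share sequence, so that reads may be divided between them, and the tissue, its cell subsets and its handling stay confounded.

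Xist had no count in skin replicates 1 to 3. It stood at 189 CPM in skin replicate 4 and at 65 to 248 CPM in the spleen libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no count in any of the 8 libraries. Whether the zeros of Xist in skin were lost transcripts was not tested.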
